A study of Mus musculus with 2 samples.

How the data were processed

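RNA sequencing was done on CT26, a mouse colon carcinoma cell line. Cells had received lentivirus for mouse Oct4 (the product of Pou5f1) and human SOX2, or lentivirus with an empty vector, and were grown for 4 days before total RNA was taken, per the labels' protocols. Libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. How poly(A) RNA was selected or ribosomal RNA removed, whether reads kept their strand, and how reads with several matches were counted are not given in the sources used here. Each group, named from the sample's genotype or treatment label, holds 1 library.

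The authors deposited 1 table of FPKM values, fragments per kilobase of gene length scaled to a common depth, for 54532 genes in both libraries, with gene length and position. CASAVA, HISAT2 and featureCounts 1.5.0-p3 on the mouse build GRCm38 were named per the submitters' processing notes. The FPKM formula and the annotation release are not given in the sources used here. Of the 54532 gene identifiers in the deposited table, 54495 were in GENCODE M21 and 53585, or 98.3%, had the same coordinates there. GENCODE M21, on the same build, was used only for exon structure and GC content.

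FPKM multiplied by the deposited gene length fell on whole multiples of 1 step per library, for 100% of the values within a tolerance of 0.001 of a read. Read numbers were recovered from these steps. They sum to 32262408 in the control library and 31521115 in the Oct4 and SOX2 library. The library totals implied by the authors' FPKM values were 0.989 and 1.01 times these sums. The ratio of the implied totals equals the median ratio of reads between the libraries over the 20110 genes with reads in both, which is what median-of-ratios size factors give. This normalization is inferred from the values, not stated in the labels.

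The measure of difference was the log2 ratio of FPKM + 1, Oct4 and SOX2 library over control, for the 12401 genes with at least 1 FPKM in at least 1 library. With this pseudocount of 1, the ratio understates the differences of low genes. No test across samples was possible with 1 library per group. Genes were counted by a rule of size, at least 2-fold either way on that scale, and 4-fold as a second level. Folds in the text are plain FPKM ratios with an exact 95% counting interval (conditional binomial, Clopper-Pearson) from the recovered reads. A fold against 0 reads was taken against a floor of 3 reads in that library and is written as at least that size. The lower limit of the exact interval, given beside it, is smaller. Intervals and floors cover counting error only, since PCR copies are not independent molecules and cultures vary.

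Before the data were examined, 33 gene lists were fixed, 28 by symbol and 5 by name pattern. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. Lists below percentile 2.5 or above 97.5 are said to lie outside the random range. The percentile describes these libraries and is not a test of the treatment. The rule for naming genes was fixed too. It takes Pou5f1 and Sox2, and the 15 highest and 15 lowest protein-coding ratios among genes with at least 5 FPKM in 1 library, without genes named only by a clone or model number. It adds from each list up to 3 genes in each direction at 2-fold or more or, where there are none, the 2 most expressed. It gave 88 genes. Any other gene in the text was chosen after its values were seen.

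The steps were tested on simulated data with Poisson counts drawn from each gene's pooled rate at the depth of each library, with 200 altered genes. Of 50 genes altered by each fold, the 2-fold rule found 0% at a true 1.5-fold, 82% at 3-fold, 94% at 4-fold and 98% at 8-fold. With counting noise alone, 37 of 11957 unaltered genes passed it, 2 of them among 9994 protein-coding genes. The intervals covered the true fold for 96.7% of 24693 genes. Of 100 unshifted random lists 5 lay outside the random range, and of 100 lists shifted by 0.3 all 100 lay above it.

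Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, centring on the median, rescaling without the 50 highest genes, protein-coding genes only, a counting interval beyond 2-fold, and random lists not matched on expression. Plain read totals and centring within 10 classes of GC content were added after the data had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.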

Results

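Gene expression was measured by RNA sequencing in CT26 mouse colon carcinoma cells carrying lentivirus for mouse Oct4 and human SOX2, and in CT26 cells carrying the empty vector. The series' title describes the first culture as de-differentiated, and the comparison addresses which transcripts differ between it and the control after 4 days. There was 1 library per group and no replicate, so the differences below compare these libraries and have no replicate check. The control library held 32262408 gene-assigned reads and the Oct4 and SOX2 library 31521115. At these depths 3 reads of a 1 kb transcript correspond to 0.0940 and 0.0942 FPKM.

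Pou5f1, the gene for Oct4, was listed at 0 FPKM with 0 reads in the control library. In the Oct4 and SOX2 library it was at 173 FPKM with 12406 reads, at least 4143-fold higher by the 3-read floor (lower 95% counting limit 3369). Pou5f1 (ENSMUSG00000024406) lies on chromosome 17 from 35506018 to 35510772 in GRCm38. Its transcript marked as principal in the annotation has 5 exons with 1056 coding bases and 306 bases of untranslated region. The vector carries mouse Oct4, so the Pou5f1 reads cannot tell the introduced copy from the endogenous gene. Mouse Sox2 was at 14.1 FPKM in the control and 23.3 FPKM in the Oct4 and SOX2 library, 1.64-fold higher (95% counting interval 1.51 to 1.79), with 929 and 1525 reads. Sox2 (ENSMUSG00000074637) is a single-exon gene on chromosome 3 from 34650405 to 34652461, and its transcript has 957 coding bases and 1100 untranslated ones. The vector carries human SOX2, so reads on mouse Sox2 can mix the endogenous gene with conserved stretches of the human one.

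The libraries differed most plainly in interferon-stimulated genes, which were lower with Oct4 and SOX2, while Myh1, Fos, Serpinb2 and Scg5 were among the genes far higher. Of 12401 genes measured, 300 were at least 2-fold higher in the Oct4 and SOX2 library, 230 at least 2-fold lower and 11871 within 2-fold. Among the 10276 protein-coding genes 143 were higher and 110 lower, of which 31 and 11 passed 4-fold. The other 2125 genes, mostly pseudogenes and noncoding RNAs, held 157 of the higher and 120 of the lower genes. With a pseudocount of 5 FPKM the counts were 75 higher and 56 lower, and with 0.1 FPKM they were 520 and 459. The median log2 ratio was -0.01 (SD 0.47 across genes), and the Pearson correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.961.

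Apart from Pou5f1, the gene furthest above the control was Myh1, a skeletal muscle myosin heavy chain. Myh1 had 0 reads in the control and 6541 reads or 32.3 FPKM with Oct4 and SOX2, at least 2184-fold higher by the 3-read floor (lower limit 1776). Kpna7, an importin alpha family member, also had 0 control reads and reached 13.2 FPKM from 1315 reads, at least 439-fold higher (lower limit 357). The protease inhibitor gene Spink10 was 111-fold higher (58.0 to 243), at 19.9 FPKM. Serpinb2, the gene for plasminogen activator inhibitor 2, was 71.3-fold higher (43.7 to 125), at 15.2 FPKM. The membrane protease gene Tmprss11d was 64.0-fold higher (37.9 to 117). Fetub, encoding fetuin B, went from 1.55 FPKM in the control to 29.0 FPKM, 18.7-fold higher (15.3 to 23.2). Mgam, encoding maltase-glucoamylase, stood at 1.09 and 20.4 FPKM, 18.7-fold higher (16.6 to 21.0). Scg5, a neuroendocrine secretory protein gene, stood at 1.86 and 42.1 FPKM, 22.7-fold higher (18.4 to 28.2). Tnfrsf11b, the gene for osteoprotegerin, was 24.7-fold higher (17.2 to 36.6). Pthlh, the gene for parathyroid hormone-like hormone, was 14.8-fold higher (10.7 to 20.9). The collagen gene Col28a1 was 87.2-fold higher (49.7 to 169) at 6.68 FPKM, and Nlrp2, of the NLR family, 75.7-fold higher (39.6 to 166) at 6.08 FPKM. Genes for muscle, endothelial and adipocyte cells had 1 measured member of 24, the cardiac troponin gene Tnnt2, at 3.46 FPKM in the control and 2.23 with Oct4 and SOX2, a log2 ratio of -0.46 at percentile 9.15.

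Fos, which encodes a subunit of the AP-1 transcription factor, was 43.3-fold higher (31.6 to 60.8), from 0.533 FPKM in the control to 23.05 FPKM. Fosb was 8.37-fold higher (7.72 to 9.10) and Egr1, an early growth response factor gene, 5.58-fold higher (5.40 to 5.76) at 176 FPKM. These, with Jun at 22.3 and 47.9 FPKM, were the 4 of 28 immediate early genes at least 2-fold higher, and none was 2-fold lower. Egr2, chosen after its value was seen, was 3.14-fold higher (2.48 to 4.01) in plain FPKM, 0.867 and 2.72, and narrowly missed the rule on the FPKM + 1 scale. The list did not stand apart as a whole: its median log2 ratio was -0.11, at percentile 11.3 of random lists, with 16 members below 0.

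At the other end, 7 of the 15 named lowest genes belonged to the interferon-stimulated list, as did 20 of the 110 protein-coding genes at least 2-fold lower. Ifit3, an antiviral effector gene, was at 35.5 FPKM in the control and 2.46 FPKM with Oct4 and SOX2, 14.4-fold lower (12.1 to 17.2). Rsad2, encoding the antiviral protein viperin, was 6.85-fold lower (6.11 to 7.69), Ifit1 5.80-fold lower (5.37 to 6.27), and Ifi44 4.91-fold lower (4.73 to 5.09) from 91.4 FPKM. Ifit3b, Cmpk2 and Oas1g were 5.05-fold, 3.94-fold and 3.504-fold lower. Outside the list, Ifi44l and Mndal were also among the lowest: Ifi44l, 12.2-fold lower (7.54 to 21.0), and Mndal, a member of the interferon-inducible p200 family, 3.82-fold lower (3.59 to 4.08). Ifit3 with Ifit3b, and Oas1a with Oas1g, are close copies whose separate values are uncertain.

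The whole interferon-stimulated list moved with these genes. Of 51 measured members 21 were at least 2-fold lower, 1 was at least 2-fold higher and 29 were within 2-fold, and 49 had a log2 ratio below 0. The median was -0.85, lower than all 10000 random lists, whose central range was -0.12 to 0.07. Of the 2 members above 0, Ifi27 passed 2-fold, at 36.1 FPKM in the control and 96.3 FPKM with Oct4 and SOX2, 2.67-fold higher (2.52 to 2.83). Summed with its related genes, the Ifi27 family stood at 188 and 197 FPKM and at 3932 and 5990 reads, and reads can be split among them. The other was Ifitm1, chosen after its value was seen, 1.91-fold higher (1.69 to 2.16). Antigen presentation genes lay lower too, with 26 of 28 below 0 and a median of -0.37 at percentile 0. On the FPKM + 1 scale only Nectin2, an immune receptor ligand gene, passed 2-fold in that list. In plain FPKM it was 2.63-fold lower (2.45 to 2.83). Cytokines and chemokines had a median of -0.25 at percentile 0.95 over 16 genes, and this left the outer range without the filter and with a filter of 5 FPKM. In that list Ccl5, a lymphocyte-attracting chemokine gene, was 3.75-fold lower (2.54 to 5.69) and Csf1, the macrophage growth factor gene, 2.07-fold lower (2.03 to 2.12) from 164 FPKM. In the same list Il1rn, the interleukin-1 receptor antagonist gene, went from 4 to 400 reads, 100.2-fold higher (38.8 to 369), and Il6 was 6.90-fold higher (4.19 to 12.03). Leukocyte markers, of which 2 of 27 were measured, gave Cd14 at 20.7 and 16.2 FPKM and Cd68 at 5.53 and 4.27 FPKM in control and Oct4 and SOX2 libraries, with a median of -0.32 at percentile 8.89.

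**Figure D1:**
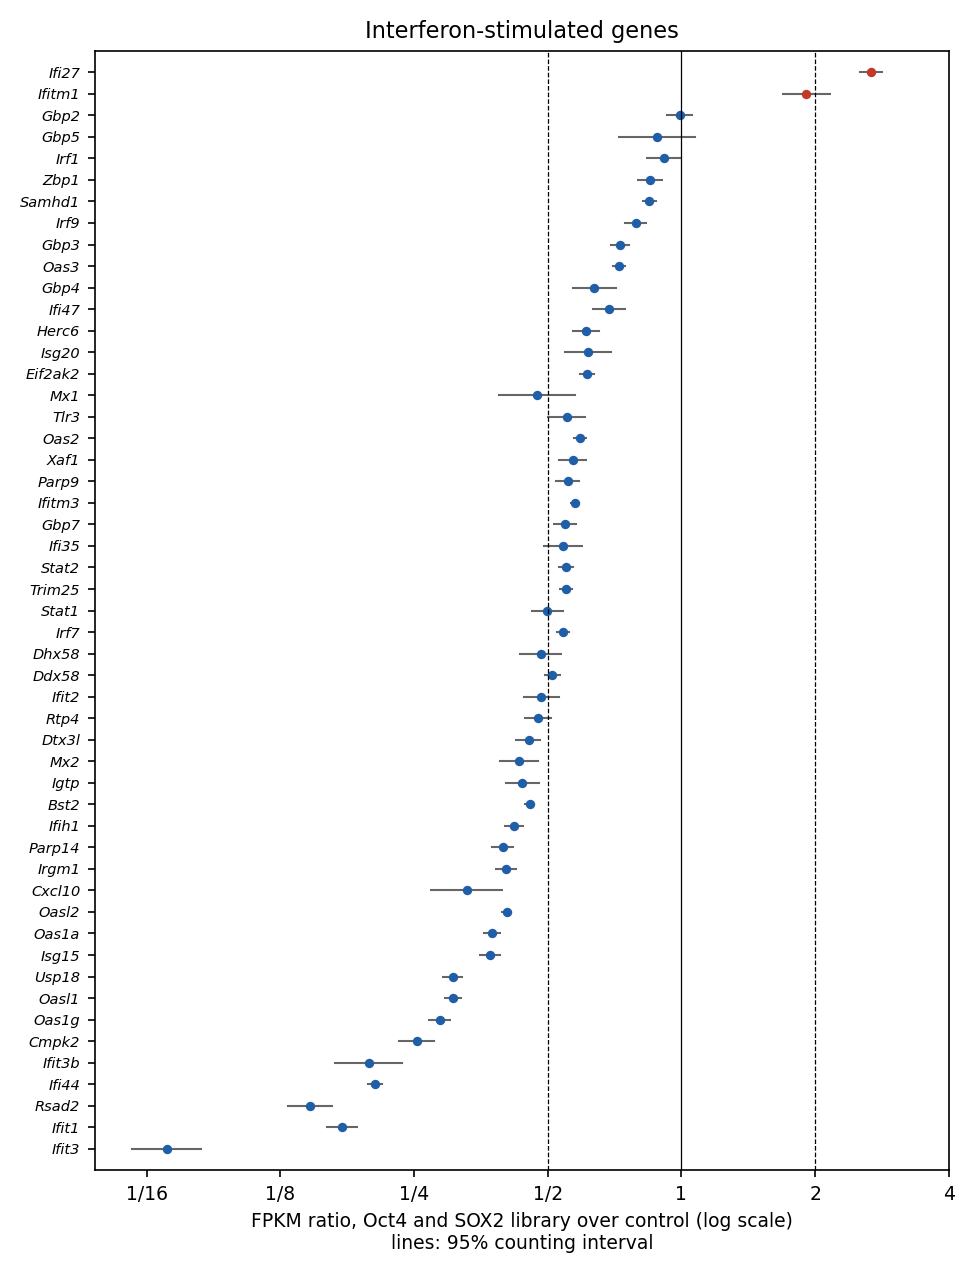
Points give the FPKM ratio of the Oct4 and SOX2 library over the control on a log axis for the 51 measured interferon-stimulated genes, 1 gene per row, and lines are 95% counting intervals; dashed lines mark 2-fold. Most genes lie left of 1, from Ifit3 at the bottom to Ifi27 at the top, which was 2.67-fold higher.

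Among the other lowest genes, Car6, a secreted carbonic anhydrase gene, was 7.60-fold lower (7.004 to 8.26) from 85.3 FPKM in the control, and Ogn, encoding the matrix proteoglycan osteoglycin, 3.64-fold lower (3.48 to 3.80) from 115 FPKM. Serpinf1, the gene for pigment epithelium-derived factor, was 8.83-fold lower (6.82 to 11.6). Avil, an actin-binding villin family member, was 7.33-fold lower (6.29 to 8.58). Cox6a2, the muscle form of a cytochrome c oxidase subunit, was 9.93-fold lower (6.10 to 17.1). Srp54b, for a signal recognition particle subunit, was 34.7-fold lower (23.7 to 52.96), while its near copy Srp54c stood at 5.26 and 5.23 FPKM. Neither copy gained reads as Srp54b went from 939 to 27: Srp54a had 33 and 18, and Srp54c 611 and 607. How reads matching several copies were counted is not given, so the Srp54b value is uncertain.

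Cell cycle genes were higher as a group by a small amount each. Of 56 measured, 54 had a log2 ratio above 0, none passed 2-fold, and the median of 0.47 lay above all 10000 random lists. The most expressed were Pcna, the replication clamp gene, at 89.8 FPKM in the control and 117 FPKM with Oct4 and SOX2, and Cdc20, a mitotic activator gene, at 89.8 and 103 FPKM. The p53 targets and cell cycle inhibitors lay lower, with a median of -0.23 at percentile 0.1 over 31 genes. Ddit4 and Gadd45a, which are stress-induced growth inhibitors, were 2.42-fold (2.26 to 2.60) and 2.39-fold lower (2.27 to 2.51), whereas Rb1, the retinoblastoma gene, was 2.79-fold higher (2.60 to 2.99). Histone genes had a median of 0.21 at percentile 99.5 over 21 measured, although H3f3c and Hist1h1c were 3.10-fold (2.01 to 4.93) and 2.31-fold lower (2.06 to 2.58). With a pseudocount of 5 the histone list returned inside the random range. The DNA methylation and chromatin list had a median of 0.12 at percentile 99.7 over 44 genes. Its only member past 2-fold was Tet2, a 5-methylcytosine dioxygenase gene, 2.83-fold higher (2.67 to 3.01).

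Metabolic lists divided. Glycolysis genes had a median of 0.32, above all random lists, with 17 of 20 above 0 and none past 2-fold; Ldha, the lactate dehydrogenase A gene, stood at 550 FPKM in the control and 698 FPKM with Oct4 and SOX2, and Pgk1 at 634 and 767. Hypoxia targets had a median of 0.42 at percentile 100 over 21 genes, with Bnip3, a mitophagy receptor gene, 2.13-fold higher (2.01 to 2.27) and Ddit4 lower. Cholesterol and lipid synthesis genes had a median of 0.30 at percentile 100 (0.18 with a pseudocount of 5), with 27 of 28 above 0, among them the desaturase genes Scd2 at 300 and 396 FPKM and Scd1 at 165 and 172 FPKM. Amino acid and unfolded protein stress genes lay the other way, with 34 of 37 below 0 and a median of -0.39 at percentile 0. Aldh1l2, of mitochondrial folate metabolism, and Ddit3, encoding the stress factor CHOP, were 2.35-fold (2.28 to 2.42) and 2.13-fold lower (2.02 to 2.25). Heat shock and oxidative stress genes had a median of 0.09 at percentile 97.9, just outside the random range and inside it under 5 alternatives. In that list Sqstm1, the autophagy receptor p62 gene, was 2.17-fold lower (2.13 to 2.21) and Gsta4, a glutathione transferase gene, 2.28-fold lower (1.92 to 2.72).

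The mitochondrial genome list had a median of -0.64 at percentile 0 over 16 genes, 4 of them at least 2-fold lower and 6 with a ratio above 0. Its protein-coding genes alone had a median of -0.27 at percentile 0.87. The mitochondrial ribosomal RNA genes mt-Rnr2 and mt-Rnr1 were 4.51-fold (4.35 to 4.68) and 4.53-fold lower (4.18 to 4.92), and mt-Nd6, for a complex I subunit, 2.505-fold lower (2.42 to 2.59). Chosen after the values were seen, mt-Nd3 was 2.66-fold lower (1.90 to 3.75), mt-Co1 stood at 3634 and 3930 FPKM, and mt-Nd4l was 2.07-fold higher (1.60 to 2.70), with a log2 ratio of 0.98 on the FPKM + 1 scale. Reads on nuclear ribosomal RNA genes were lower as well, at 19568 in the control and 8387 with Oct4 and SOX2. Nearly all of them, 19443 and 8267, lay on the entry CT010467.1. Nuclear-encoded oxidative phosphorylation genes had a median of 0.01 at percentile 90.5 over 94 genes, with Cox6a2 the member at least 2-fold lower. Its 2-fold higher member was the pseudogene Atp5k-ps2, from 4 to 18 reads. Ribosomal protein genes had a median of -0.15 at percentile 1.16 over 84, none past 2-fold, with Rplp1 at 2232 and 1941 FPKM and Rps3a1 at 1316 and 1164 FPKM. Housekeeping genes had a median of -0.03 at percentile 61.0 over 20, with Eef1a1 at 3259 and 3126 FPKM and Eef2 at 1385 and 1306 FPKM.

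**Figure D2:**
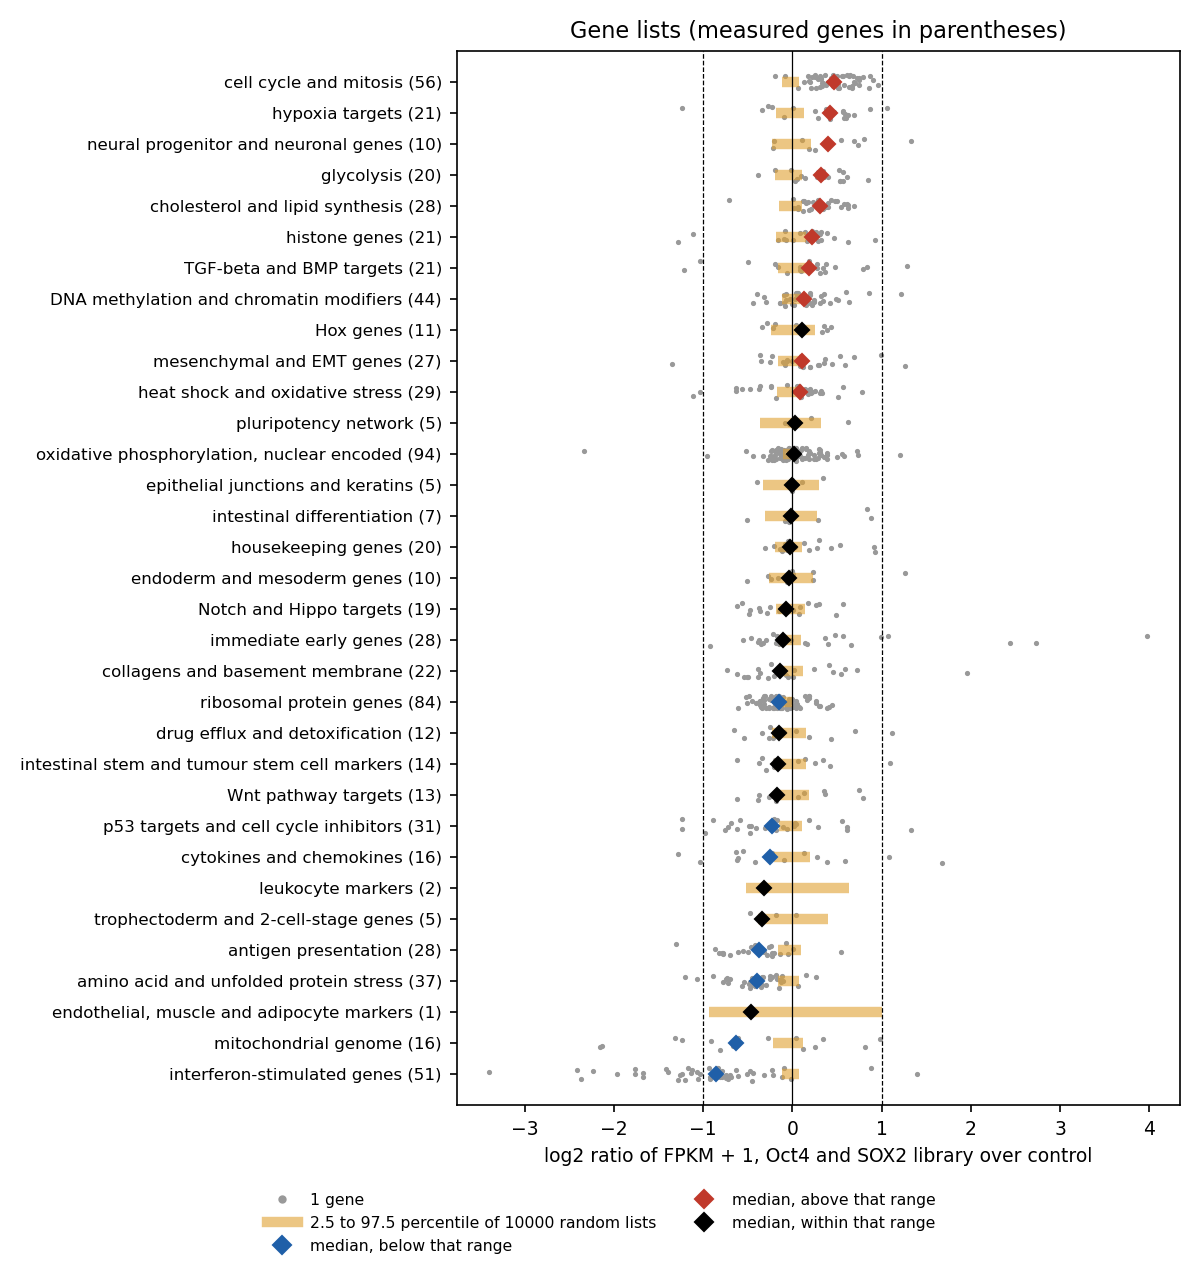
Gray points are the log2 ratios of FPKM + 1, Oct4 and SOX2 library over control, for the measured genes of 33 lists, 1 list per row with its gene number, diamonds are list medians, and orange bars span the 2.5 to 97.5 percentiles of 10000 random lists matched on expression. The medians run from -0.85 for interferon-stimulated genes to 0.47 for cell cycle genes, and 7 lie below and 10 above their orange bars.

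The pluripotency network gave no comparable difference. Of its 40 genes 5 reached 1 FPKM in either library, none was 2-fold different, and the median was 0.03 at percentile 66.6. Klf4, a reprogramming factor gene, stood at 78.2 FPKM in the control and 73.8 FPKM with Oct4 and SOX2, and Klf5 at 18.8 and 19.3 FPKM. Nanog, a core pluripotency factor gene chosen here after its value was seen, had 2 reads in the control and 0 with Oct4 and SOX2. Of the 40 genes, 24 had 0 reads in the control and 26 had 0 with Oct4 and SOX2. A gain or a loss below 1 FPKM was outside the measured set. Examples chosen after their values were seen are Dnmt3l, with 34 reads in the control and 0 with Oct4 and SOX2, and Dppa2, with 23 and 6. Fut4 went the other way, with 10 and 35.

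Neural genes had a median of 0.40 at percentile 99.93 over 10 measured of 39, and medians from 0.12 with no filter to 0.69 with a filter of 5 FPKM, with Tubb3, a neuronal tubulin gene, 3.08-fold higher (2.57 to 3.71). Mesenchymal genes had a median of 0.11 at percentile 98.1 over 27, a median of 0.05 with no filter, and percentile 95.6 against unmatched lists. In that list Twist1, a mesenchymal transcription factor gene, was 2.43-fold higher (2.31 to 2.56) at 97.6 FPKM and Pdgfrb, a growth factor receptor gene, 2.85-fold lower (2.64 to 3.09). Collagens and basement membrane genes had a median of -0.14 at percentile 6.17 over 22, with Col5a2 14.8-fold higher (11.8 to 18.7). The TGF-beta and BMP list had a median of 0.19 at percentile 99.1 over 21 genes and lost its place outside the random range under 3 alternatives. Bmpr2, a BMP receptor gene, was 2.64-fold higher (2.54 to 2.73), Grem1, a BMP antagonist gene, 2.41-fold lower (2.29 to 2.54) and Id3 2.58-fold lower (2.06 to 3.23). Endoderm and mesoderm genes had a median of -0.03 at percentile 42.9 over 10, with Twist1 again the member past 2-fold. Hox genes had a median of 0.11 at percentile 82.3 over 11, with Hoxc6 at 18.1 and 14.6 FPKM and Hoxa5 at 4.62 and 6.09 FPKM. Trophectoderm and 2-cell-stage genes had a median of -0.34 at percentile 4.07 over 5, with Eif1a at 112 and 80.5 FPKM and Usp17la at 9.34 and 8.09 FPKM.

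Intestinal and epithelial lists lay inside the random range. Epithelial junction and keratin genes, 5 measured of 44, had a median of 0.00 at percentile 54.4, with Cldn12 at 64.0 and 69.0 FPKM and Tjp1 at 37.6 and 37.5 FPKM. Intestinal differentiation genes, 7 measured of 36, had a median of -0.01 at percentile 53.2, with Krt20, a differentiated-enterocyte keratin gene, at 14.9 and 28.3 FPKM. Intestinal and tumour stem cell markers had a median of -0.16 at percentile 7.32 over 14, and Anxa1, the annexin A1 gene, was 2.14-fold higher (2.10 to 2.19) at 335 FPKM. Wnt targets had a median of -0.17 at percentile 5.39 over 13, with Ccnd1 at 142 and 182 FPKM and Myc at 50.3 and 44.4 FPKM. Notch and Hippo targets had a median of -0.08 at percentile 24.8 over 19, with Axl at 226 and 240 FPKM and Ajuba at 60.9 and 46.7 FPKM. Drug efflux and detoxification genes had a median of -0.16 at percentile 11.2 over 12, and Aldh3a1, an aldehyde dehydrogenase gene, was 2.27-fold higher (2.07 to 2.49). Of the 33 lists 7 lay below and 10 above the random range. Chance alone would place 1.65 in all outside it if the genes within a list varied independently. Genes of a list can vary together, so that number may be too low.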

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

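Plain library totals and GC centring were chosen after the data had been seen, and the other alternatives before. No list outside the random range changed sign under any setting run. Counts of genes depended most on how low values were treated. Genes at least 2-fold higher numbered 300, and 520 with a pseudocount of 0.1, 75 with 5, 145 with a filter of 5 FPKM and 143 among protein-coding genes. Genes at least 2-fold lower numbered 230, and 459, 56, 121 and 110 in the same order. The last pair of settings tests fewer genes, and a larger pseudocount shrinks low ratios by construction. The other settings left both counts within 1.5 times, including 239 and 193 whose counting interval lay beyond 2-fold. For lists, 315 of the alternative values stayed on their side of the random range, 12 returned inside it and 2 went outside. Mesenchymal genes (0.11) returned inside with unmatched lists. Cytokines returned with no filter (-0.080) and with 5 FPKM (-0.25). Heat shock genes returned with no filter (0.048), with 5 FPKM, protein-coding genes and unmatched lists (each 0.087) and GC centring (0.083). TGF-beta and BMP genes returned with a pseudocount of 5 (0.093), no filter (0.10) and 5 FPKM (0.10), and histone genes with a pseudocount of 5 (0.073). Trophectoderm and 2-cell-stage genes went below the random range with no filter (-0.11) and among protein-coding genes (-0.34). Inside the range, 16 values of 8 lists changed sign. The pluripotency list did with no filter (-0.037), as did intestinal stem markers (0.0004) and Wnt targets (0.0001), and with 5 FPKM Hox genes (-0.22) and endoderm and mesoderm genes (0.0011). Epithelial genes (0.013 to 0.052) and intestinal differentiation genes (0.0041 to 0.099) did under the scalings and 5 FPKM, the former also with GC centring, and housekeeping genes under rescaling (0.0041) and plain totals (0.0017). Staying outside the range but moving by over 1.5 times were mesenchymal (0.050) and histone genes (0.092) with no filter, TGF-beta and BMP genes with a pseudocount of 0.1 (0.28), cholesterol (0.18) and neural genes (0.23) with one of 5, neural genes also with no filter (0.12) and 5 FPKM (0.69), and the mitochondrial genome among protein-coding genes (-0.27). For these lists the cause was not tested. Interferon-stimulated, cell cycle, stress and metabolic list calls did not depend on any setting run, heat shock aside. Of the named genes 61 were past 2-fold, 61 with centring, rescaling or a pseudocount of 0.1, and 43 with a pseudocount of 5. Centring moved all log2 ratios by 0.02, while rescaling and plain totals each moved the FPKM ratio by 0.03 on the log2 scale and the ratio of FPKM + 1 by less in low genes. The filter of 5 FPKM left no measured gene in the endothelial, muscle and adipocyte list. No paired analysis was possible because each group holds 1 library, and no replicate could be left out. Depth limits genes near 1 FPKM, where 3 reads of a 1 kb transcript equal 0.094 FPKM.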

Other observations

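All tests in this part were chosen after the results had been seen. Several genes for secreted or adhesion proteins, outside the lists and picked after their values were seen, with no test of the group, were higher with Oct4 and SOX2. Vcam1, a leukocyte adhesion receptor gene, stood at 11.5 FPKM in the control and 78.9 FPKM, 6.85-fold higher (95% counting interval 6.61 to 7.11), and the E-selectin gene Sele at 13.4 and 43.5 FPKM. Thbs2, the thrombospondin 2 gene, went from 37.6 to 181 FPKM, 4.82-fold higher (4.70 to 4.93), and Esm1, an endothelial proteoglycan gene, from 82.2 to 355 FPKM. Edn1, the endothelin 1 gene, was 5.63-fold higher (4.75 to 6.71) and Angptl4 5.42-fold higher (4.56 to 6.49).

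Genes upstream of the interferon response were close between the libraries. Ifnar1 stood at 9.76 FPKM in the control and 10.6 FPKM with Oct4 and SOX2, Ifnar2 at 5.90 and 5.75, Jak1 at 19.2 and 20.04, and the feedback inhibitor gene Socs1 at 2.74 and 2.69. Ifnb1, for interferon beta, had 6 and 4 reads, too few to show a difference. The classical class I genes H2-K1, at 80.8 and 81.4 FPKM, and H2-D1, at 349 and 333, differed little beside Cd274, the PD-L1 gene. Cd274, of the antigen presentation list, was 2.04-fold lower (1.76 to 2.37) in plain FPKM. On the FPKM + 1 scale its log2 ratio was -0.79, short of the 2-fold rule.

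The lower interferon-stimulated genes were set against 2 explanations. Reads shared between near-identical interferon genes would cancel when families are summed. With each family of close copies summed, the median over 40 values was -0.86. Most of these values are single genes that summing leaves unchanged, so the median alone says little about sharing. The single genes, outside the summed families, ran from -2.37 for Rsad2 to -0.12 for Irf1, all below 0. The summed families themselves ranged from -2.43 for Ifit, from 9084 to 1876 reads, to 0.07 for Ifi27, the only family above 0. These values argue against sharing within the summed families as the source of the lower list, Ifi27 aside. A candidate explanation is an effect of the forced factors, but with 1 library per group it cannot be told apart from another difference between the cultures, such as vector dose.

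The lower ribosomal RNAs and mt-Nd6 were set against loss of whole RNA classes. Less carry-over of all RNAs without poly(A) tails would lower replication-dependent histone genes. The 11 measured had a median log2 ratio of 0.16, with 10 above -0.5. Cell cycle genes were higher in the same library, and more histone RNA from dividing cells could mask a loss, so these values cannot decide. Reads on small nuclear RNA genes numbered 488 and 481 and on small nucleolar RNA genes 1864 and 2483, whereas those on microRNA genes (18461 and 11671) and mitochondrial tRNA genes (88 and 49) were lower. Lower mitochondrial RNA content by the size seen in mt-Rnr1 and mt-Rnr2 would lower all 12 heavy-strand mitochondrial mRNAs, which ranged from -1.24 to 0.98 with a median of -0.11. Both extremes, mt-Nd3 and mt-Nd4l, were genes of low level. Among the most abundant, mt-Cytb stood at 0.34, mt-Nd4 at 0.25, mt-Co1 at 0.11 and mt-Nd2 at 0.04. The abundant mt-Nd1 and mt-Nd5 stood at -0.61 and -0.66. Less carry-over of RNAs without poly(A) tails, a smaller loss of mitochondrial RNA and a loss of some RNA classes stay open. A difference in removal of ribosomal RNA or in the cells stays open too.

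The 30 protein-coding genes at least 4-fold higher besides Pou5f1 had higher neighbours more frequently than random sets: 8 had a non-overlapping gene within 100 kb whose own counting interval lay above 2-fold, against a median of 2 and a 97.5 percentile of 5 in 10000 random sets of measured protein-coding genes. Examples are Rarres1 with Lxn (26.3 and 79.4 FPKM) and Mlf1, Fetub with Ahsg (0 and 61 reads), and Myh1 with Myh2 (0 and 282 reads), although Spink10 and Gm17732 count each other and myosin copies can share reads. The 11 protein-coding genes at least 4-fold lower showed the same kind of excess, 6 with a lower neighbour against a random median of 1, largely in the Ifit and Ifi44 clusters. Local activation cannot be told apart from the clustering of related genes, which the random sets do not match. Skeletal muscle cells as a source of Myh1 would bring other muscle transcripts, yet the highest of 9 outside the myosin cluster, Acta1, was 0.266 FPKM beside 32.3 for Myh1 and 1.24 for its neighbour and close copy Myh2.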
